A study of Danio rerio with 5 samples.

How the data were processed

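The series profiled 2 chromatin marks in whole zebrafish embryos (a mixture of the AB and Tübingen strains, per the labels). H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complex 2 deposits, was measured by ChIP-seq at dome stage, a late blastula stage, and at 48 hours post fertilisation (48 hpf). DNA methylation was measured by MethylCap-seq, in which methylated DNA fragments are captured with a methyl-CpG binding protein and sequenced, at dome stage, 24 hpf and 48 hpf. There were 5 samples in 5 groups, with 1 library per group. No value in the text therefore has a replicate spread, and no p-value was computed between stages or marks.

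The starting material was 1 list of peaks per library, as the authors deposited it. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie2 2.2.1, SAMtools and MACS2, and the build was danRer7, the UCSC name of the Zv9 assembly. Their parameters, their roles, the use of an input library as control, and the pooling of replicates before peak calling were not given in the sources used here. The H3K27me3 lists had the 9-column layout that MACS2 writes for broad peaks, in which the values of a peak are averages over its length. The MethylCap lists had the 10-column layout for narrow peaks, with the position of the summit in the last column of the deposited file, which was not used. Peak shape and width were therefore compared only within a mark. The fold enrichment in the deposited lists is the enrichment over the local background that the caller used. Only in the H3K27me3 lists is it an average over the peak, so folds of the 2 marks are not like measures. The deposited −log10 p and −log10 q values are those of the peak caller. The deposited score was 10 times the −log10 q value without its decimals in every peak, except in 6 peaks of the MethylCap dome list. These values are the authors' and were used to describe, rank or filter peaks within a list. Where folds from 2 lists are printed for the same site, they describe that site, and their difference was not tested. The lowest −log10 q values were 1.01 in both H3K27me3 lists and 1.63, 1.34 and 1.32 in the MethylCap lists of dome, 24 hpf and 48 hpf.

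The lists hold no read counts, so sequencing depth was unknown. The number of peaks that a caller finds grows with depth and enrichment, and a region without a peak may have been below the detection limit rather than free of the mark. MethylCap-seq also responds to the density of methylated CpG, so that sparsely spaced methylated CpGs can be missed.

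Peaks on the 25 numbered chromosomes were used, and the few on the mitochondrial genome were set aside. Peaks were called shared when they overlapped by at least 1 bp. Each share of peaks has a Wilson 95% confidence interval, which covers counting error only and treats peaks as independent. As a background, the second list of each pair was moved as a whole around each chromosome 100 times, by at least 100 kb and with a fixed random seed, and the share was counted again. The mean and the standard deviation (SD) of these moves are given, and the ratio is the observed share divided by that mean. The end of a chromosome was taken as the highest peak end in any list, which gave 1357 Mb in all. Unassembled stretches were thus part of the space that peaks were moved over. A standard error (SE) with a ratio is a jackknife over the 25 chromosomes and describes precision within a library, not between embryos. MethylCap coverage around the centres of H3K27me3 peaks was averaged in bins of 500 bp up to 10 kb on both sides. The MethylCap lists were merged into 1 set of regions, each described by the stages with a peak in it. To describe wide H3K27me3 domains, peaks within 5 kb of each other were joined; this step, the division of chromosome 4 by position, a repeat without chromosome 4 and moves of 10 to 50 kb were chosen after the data were examined.

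Regions are named by coordinates on danRer7, counted from 1. The rule, fixed before the data were examined, took the 5 peaks with the highest score and the 5 widest per pattern (dome only, both stages, 48 hpf only, both marks, H3K27me3 alone), and the text prints a selection of them. For patterns found at both stages, the order by the sum of ranks was chosen afterwards. A genome sequence and a gene annotation of danRer7 were not used here. The planned counts of promoters with each mark, the gene lists (Hox genes, developmental transcription factors, signalling ligands and antagonists, housekeeping, germline, early zygotic and differentiation genes) and the split of peaks by CpG content were therefore not analysed here, and no gene is assigned to a region.

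Fixed beforehand, the other settings tried were an overlap of at least 50% of the shorter peak, the higher-scoring 50% of each list, lists of the same mark reduced to equal numbers of peaks, peaks joined within 1 kb, all sequences, and independent random placement of each peak. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For H3K27me3 with MethylCap at dome and at 48 hpf, 3 results were checked with bedtools 2.31.1. These were the overlap count, the covered bases and the count at 50% of the shorter peak. The procedure was tested on simulated lists, in which peaks of the deposited widths were scattered at random along each chromosome. With 20% of 31983 simulated dome H3K27me3 peaks placed on simulated MethylCap peaks, 20.2% was recovered, and with none placed 0.070%. For 6434 simulated peaks of 48 hpf the recovered shares were 20.2% and 0.44%. The simulated lists lacked the clustering of real peaks, so the test did not show how the moved positions behave under clustering.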

Results

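Peak lists of 5 libraries described H3K27me3 at dome and 48 hpf and DNA methylation at dome, 24 hpf and 48 hpf in whole zebrafish embryos. The H3K27me3 list of dome held 31983 peaks on the numbered chromosomes, which covered 17.9 Mb, or 1.32% of the chromosome span, with a median width of 397 bp. The list of 48 hpf held 6434 peaks, which covered 6.39 Mb (0.471%) with a median width of 760 bp. MethylCap peaks were far more numerous. They numbered 220564 at dome (97.4 Mb, 7.18%), 330176 at 24 hpf (118.9 Mb, 8.76%) and 192673 at 48 hpf (72.0 Mb, 5.30%). With 1 library per group, the differences below have no replicate check and no p-value. Intervals in parentheses are Wilson 95% intervals for counting error only. Sequencing depth was unknown, so differences in peak number between stages could not be separated from differences in depth or enrichment.

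The first comparison asked which H3K27me3 sites of the blastula were also marked in the embryo of 48 hpf. Most 48 hpf sites had a dome peak, whereas most dome sites had no 48 hpf peak. Of the 48 hpf peaks, 4680 of 6434 (72.7%, 71.6 to 73.8%) overlapped a dome peak, against 3.6% ± 0.20 (SD of 100 moves) when the dome list was moved along the chromosomes. Of the dome peaks, 4987 of 31983 (15.6%, 15.2 to 16.0%) overlapped a 48 hpf peak, against 0.727% ± 0.044 for moved positions. The ratios to moved positions were 20.2 (SE 0.44) and 21.5 (SE 0.45).

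Most of the wide H3K27me3 domains held peaks at both stages. After peaks within 5 kb were joined, 202 domains of dome and 66 of 48 hpf were at least 10 kb wide. All 66 domains of 48 hpf met dome peaks, and 180 of the 202 dome domains met 48 hpf peaks. These counts were not compared with moved positions, and a wide domain meets other peaks more readily than a single peak does. The widest dome domain lay on chromosome 23 from 36093694 to 36174129 and joined 27 peaks over 80.4 kb, of which 39.8% was in dome peaks and 7.58% in 48 hpf peaks. A dome domain of 66.4 kb with 24 peaks lay on chromosome 3 from 23968898 to 24035317. The widest 48 hpf domain, of 47.0 kb, lay on chromosome 12 from 15431115 to 15478110, and its bases were 41.1% in dome peaks and 51.9% in 48 hpf peaks. The widest single peak of 48 hpf spanned 10493 bp on chromosome 16 from 20311328 to 20321820, where the dome list held a series of narrower peaks.

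**Figure D1:**
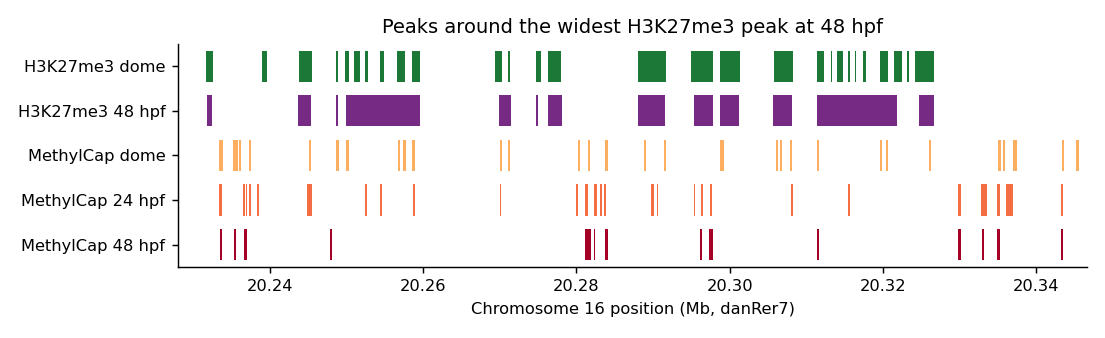
Peaks of the 5 libraries around the widest H3K27me3 peak of 48 hpf, by position on chromosome 16 in Mb (danRer7); each bar is 1 peak drawn to scale, with 1 row per library. The window holds 28 H3K27me3 peaks of dome and 13 of 48 hpf, and 30, 28 and 15 MethylCap peaks of dome, 24 hpf and 48 hpf.

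Shared and stage-specific peaks differed in width and significance. The 26996 dome-only peaks had a median width of 345 bp and a median −log10 q of 1.48, and the 4987 shared dome peaks 989 bp and 3.91. At 48 hpf the 1754 peaks without a dome peak had a median width of 505 bp, and the 4680 shared peaks 904 bp. In the lowest decile of the dome list by −log10 q, 1.59% (1.21 to 2.09%) of peaks were shared, and in the highest decile 69.4% (67.8 to 71.0%). For the 48 hpf list the corresponding shares were 42.9% (39.1 to 46.7%) and 95% (93.1 to 96.5%).

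**Figure D2:**
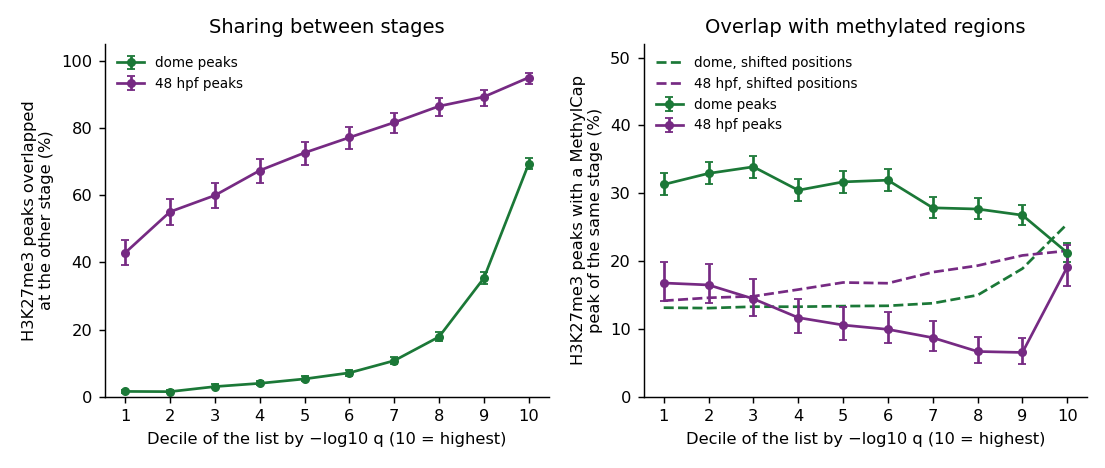
Left, percentage of H3K27me3 peaks overlapped at the other stage, and right, percentage overlapped by a MethylCap peak of the same stage, for deciles of each list by −log10 q (10 is the highest); points are shares, bars Wilson 95% intervals, and dashed lines the mean of 100 moved positions. Sharing between stages rises to 69.4% for dome and 95% for 48 hpf, and overlap with MethylCap peaks lies above moved positions in deciles 1 to 9 of the dome list, and below them in decile 10 of the dome list and deciles 4 to 9 of the 48 hpf list, by more than the intervals.

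Among the strongest sites found at both stages was a 558 bp dome peak on chromosome 5 from 64236657 to 64237214, with a fold enrichment of 14.4 in the dome list and 11.3 in the 48 hpf list. Another, on chromosome 20 from 4645222 to 4645742, had a fold of 14.4 at dome and 11.6 at 48 hpf. Both sites also held a MethylCap peak at 24 hpf. The widest pair of peaks lay on chromosome 16, from 16634962 to 16641198 at dome and from 16634968 to 16640640 at 48 hpf, with a fold of 1.60 and 1.61. The highest-scoring dome-only peak (chromosome 1, 3370422 to 3370729, fold 10.2) and the highest-scoring 48 hpf-only peak (chromosome 23, 35153022 to 35153285, fold 8.98) were narrow and held MethylCap peaks at all 3 stages. A 1398 bp dome-only peak on chromosome 5 from 74573096 to 74574493 (fold 5.11) and a 723 bp 48 hpf-only peak on chromosome 21 from 1411137 to 1411859 (fold 6.73) held none. The widest dome-only peak spanned 5601 bp on chromosome 14 from 2844395 to 2849995, inside a domain of 61.7 kb in which 1.26% of bases lay in 48 hpf peaks.

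The asymmetry between the stages depended on the lengths of the lists. With the dome list reduced to its 6434 highest-scoring peaks, 52.2% of dome peaks and 49.4% of 48 hpf peaks were shared. In the full lists the numbers of overlapped peaks were similar, 4987 at dome and 4680 at 48 hpf. Lists of equal length therefore give similar shares by construction. The reduced list thus cannot show whether dome sites were lost by 48 hpf.

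The next comparison followed DNA methylation from dome to 48 hpf. Many methylated regions were called at every stage, and the 24 hpf list added the largest number found at 1 stage alone. The merged lists gave 373137 regions, of which 118048 (31.6%, 31.5 to 31.8%) had a peak at all 3 stages. These were the widest regions, with a median of 587 bp, and covered 78.3 of the 162.7 Mb. A merged region spans every peak in it, so regions with peaks of more stages tend to be wider by construction. Before merging, dome peaks found at both other stages had a median width of 447 bp, and those found at no other stage 287 bp. Regions called at 24 hpf alone numbered 106790 (28.6%), at dome alone 26932 (7.22%) and at 48 hpf alone 21214 (5.69%). Dome and 24 hpf shared 57575 regions that had no 48 hpf peak, 24 hpf and 48 hpf shared 31728 without a dome peak, and 10850 had peaks at dome and 48 hpf but not at 24 hpf.

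**Figure D3:**
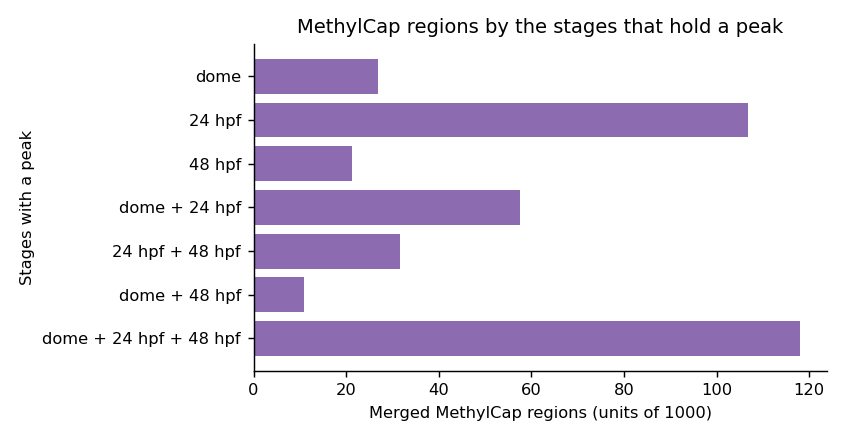
Number of merged MethylCap regions (in units of 1000, horizontal axis) by the stages at which a peak was called in them (vertical axis), 1 library per stage. The bars for all 3 stages (118048 regions) and for 24 hpf alone (106790 regions) are the longest.

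Of the dome MethylCap peaks, 82.4% (82.2 to 82.5%) overlapped a 24 hpf peak and 60.3% (60.1 to 60.5%) a 48 hpf peak, against 18.6% ± 0.111 and 11.2% ± 0.095 for moved positions (SD). Of the 24 hpf peaks, 48.2% (48.1 to 48.4%) overlapped a 48 hpf peak, against 10.1% ± 0.063. In the opposite direction, 82.1% of 48 hpf peaks overlapped a 24 hpf peak and 71.3% a dome peak. These shares depended on the lengths of the lists. With equal peak numbers, 62.3% of dome peaks overlapped a 24 hpf peak and 63.0% a 48 hpf peak, and the ratios to moved positions for the full lists were 4.43 and 5.40. In the highest decile of the dome list by −log10 q, 97.0% of peaks were shared with 24 hpf, 90.9% with 48 hpf, and 1.23% with neither. Dome peaks found at both other stages had a median fold of 4.45, and those found at no other stage 3.69.

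The most significant MethylCap regions of both dome and 48 hpf lay on chromosome 22 from 42253348 to 42255143 (fold 7.92 at dome and 8.39 at 48 hpf) and on chromosome 7 from 35921482 to 35923142 (fold 8.47 and 9.15), and both overlapped H3K27me3 peaks of the 2 stages. A few strong dome peaks had no later call. Peaks on chromosome 23 from 22487753 to 22488309 (fold 8.94, −log10 q 69.3) and from 22473050 to 22473436 (fold 7.45, −log10 q 61.2), and on chromosome 13 from 48684651 to 48685037 (fold 7.80, −log10 q 54.4), had no MethylCap peak at 24 or 48 hpf. Strong 48 hpf peaks without a dome peak included chromosome 20 from 33703888 to 33704271 (fold 11.7) and chromosome 7 from 17563431 to 17563914 (fold 11.4), and both had a peak at 24 hpf.

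The third comparison asked how the marks were distributed relative to each other at dome and 48 hpf. Taken as whole lists, H3K27me3 peaks overlapped MethylCap peaks more often than moved positions did at dome, and less often at 48 hpf. Of the dome H3K27me3 peaks, 9457 of 31983 (29.6%, 29.1 to 30.1%) held a MethylCap dome peak, against 15.3% ± 0.224 (SD; range of 100 moves 14.7 to 15.8%), a ratio of 1.94 (SE 0.051). Of the 48 hpf H3K27me3 peaks, 778 of 6434 (12.1%, 11.3 to 12.9%) held a MethylCap 48 hpf peak, against 17.3% ± 0.486 (range 16.0 to 18.8%), a ratio of 0.699 (SE 0.045). MethylCap peaks covered 16.0% of the bases in H3K27me3 peaks at dome and 4.52% at 48 hpf, against 7.18% and 5.30% of the chromosome span. The deficit at 48 hpf was thus milder by bases than by counts of peaks.

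The most significant dome peaks went the other way. In the highest decile of the dome list by −log10 q, 21.2% (19.9 to 22.7%) held a MethylCap peak, against 25.5% for moved positions (ratio 0.833). The ratio of the 48 hpf list also fell with significance up to decile 9. It was 1.18 in decile 1 (16.8%, 14.1 to 19.9%, against 14.2%) and 0.31 in decile 9 (6.53%, 4.87 to 8.71%, against 20.8%). In decile 10 it was 0.889 (19.1%, 16.3 to 22.3%, against 21.5%). By their intervals, deciles 1 and 10 were not distinguishable from moved positions.

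The excess at dome came from peaks without a 48 hpf counterpart. Of the 26996 dome-only peaks, 32.5% (32.0 to 33.1%) held a MethylCap dome peak, against 13.8% for moved positions (ratio 2.35, SE 0.041). Of the 4987 dome peaks shared with 48 hpf, 13.6% (12.6 to 14.5%) did, against 23.0% (ratio 0.589, SE 0.061). At 48 hpf the shared peaks had a ratio of 0.623 (SE 0.056), and the 48 hpf-only peaks a ratio of 0.991 (SE 0.049), which was not distinguishable from moved positions. Of the bases in shared peaks, 6.04% at dome and 4.29% at 48 hpf lay in MethylCap peaks, against 7.18% and 5.30% of the chromosome span. The deficit in shared peaks was therefore also milder by bases than by counts. No MethylCap peak at any stage was present in 82.2% of the shared dome peaks and in 54.6% of the dome-only peaks. With the dome H3K27me3 list reduced to its 6434 most significant peaks, the ratio at dome was 1.09 (SE 0.082), which was not distinguishable from moved positions. With the lists of each mark reduced to equal numbers of peaks it was 1.1.

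Around dome-only H3K27me3 peaks, MethylCap peaks covered 21.0% (SE 0.57) of bases at the peak centre and 7.67% and 7.57% at 10 kb before and after it. Around shared peaks the coverage at dome was 7.21% (SE 0.79) at the centre, lower at 1.5 kb on both sides (3.63%, SE 0.19), and 6.78% and 6.37% at 10 kb before and after it. Around the shared peaks of 48 hpf, MethylCap peaks of 48 hpf covered 6.24% (SE 0.70) at the centre, 2.79% (SE 0.19) at 1.5 kb and 4.38% and 4.55% at 10 kb before and after it. The 48 hpf-only peaks had 6.28% (SE 0.44) at the centre, 3.17% (SE 0.20) at 1.5 kb, and 5.48% (SE 0.35) and 4.05% (SE 0.42) at 10 kb before and after it.

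**Figure D4:**
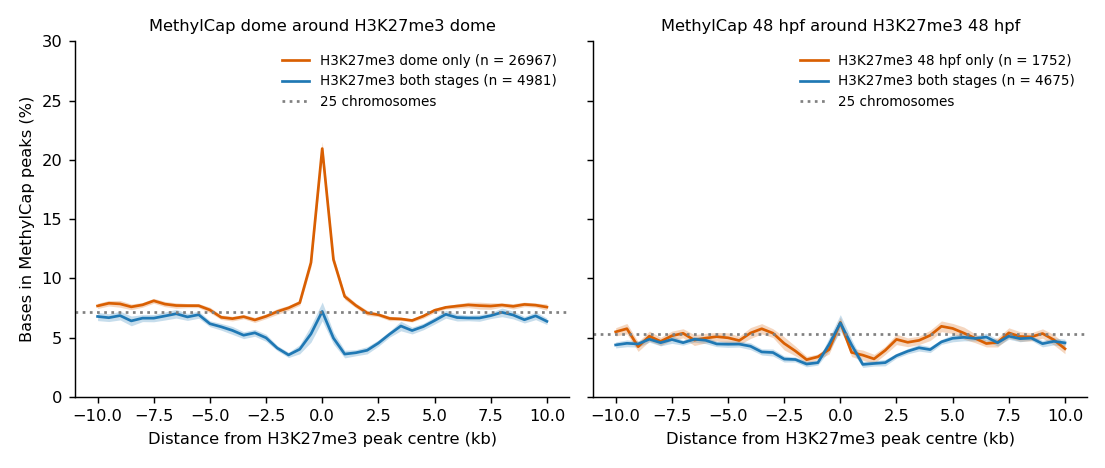
Percentage of bases in MethylCap peaks of the same stage (vertical axis) by distance from the centre of H3K27me3 peaks in kb (horizontal axis, bins of 500 bp), at dome (left) and 48 hpf (right), for peaks found at 1 stage and at both; shading is ±1 jackknife SE over chromosomes, and the dotted line is the coverage of all 25 chromosomes. At dome, dome-only peaks reach 21.0% at the centre and peaks found at both stages 7.21%, with a depression on both sides; at 48 hpf both groups have such a depression and similar central values of 6.28% (48 hpf only) and 6.24% (both stages).

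Wide H3K27me3 domains were poor in MethylCap peaks. In the 202 dome domains of at least 10 kb, MethylCap dome peaks covered 3.21% of bases, against 7.15% ± 0.381 (SD) for moved positions, and in the 66 domains of 48 hpf, MethylCap 48 hpf peaks covered 1.88%, against 5.33% ± 0.512. Of the 10 widest dome domains, 6 held no MethylCap peak at any stage, the domains on chromosomes 23 and 3 given above among them. Of the 10 widest 48 hpf domains, 0 were without a MethylCap peak at every stage, and the one on chromosome 7 from 54460516 to 54485750 had 7.20% of its bases in MethylCap peaks of 48 hpf. The strongest H3K27me3 peaks with MethylCap at the same stage included chromosome 15 from 36921 to 37338 at dome (H3K27me3 fold 9.05, MethylCap fold 6.57) and chromosome 9 from 16015282 to 16016508 (6.38 and 10.9). Those without it at either stage included chromosome 2 from 135064 to 135753 (H3K27me3 fold 10.3 at dome). Among H3K27me3 peaks in the upper 1% by fold enrichment, 35.3% of 320 at dome and 43.1% of 65 at 48 hpf held a MethylCap peak, against 29.5% and 11.8% of the other peaks.

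Few shared H3K27me3 sites without a MethylCap call at dome had one at 48 hpf. A call at 1 stage only may reflect the detection limit of a single library rather than a change in methylation. Of the shared dome peaks without MethylCap at dome, 103 of 4311 (2.39%, 1.97 to 2.89%) held a MethylCap peak at 48 hpf, and of the dome-only peaks 1579 of 18215 (8.67%, 8.27 to 9.09%). The same peaks moved along the chromosomes gave 5.91% ± 0.352 for the shared and 3.67% ± 0.145 for the dome-only peaks (SD of 20 moves). Of the dome H3K27me3 peaks with a MethylCap dome peak, 24.0% (20.9 to 27.3%) of the shared and 26.2% (25.3 to 27.1%) of the dome-only ones had none at 48 hpf, against 36.7% ± 1.38 and 42.1% ± 0.760 for their moved positions.

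Chromosome 4 stood apart from the other chromosomes. Its long arm is known in zebrafish to be rich in repeats and heterochromatin. The chromosome held 34.3 dome H3K27me3 peaks per Mb, against 20.3 to 26.6 on the others, and was the only chromosome on which the overlap of the marks at 48 hpf exceeded moved positions (ratio 1.60, others 0.481 to 0.920). From 30 Mb to its end, 50.1% (47.5 to 52.6%) of 1448 dome H3K27me3 peaks and 52.1% (43.2 to 61.0%) of 117 peaks of 48 hpf held a MethylCap peak of the same stage. Against moves of 10 to 50 kb these shares had ratios of 2.45 at dome and 2.69 at 48 hpf, compared with 1.69 and 0.301 below 25 Mb and 1.84 and 0.696 on the other chromosomes. Below 25 Mb the shares were 20.8% (17.5 to 24.5%) of 514 and 3.70% (1.45 to 9.14%) of 108. This part of the sequence is repetitive, and how reads with several mapping positions were treated was not given in the sources used here.

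**Figure D5:**
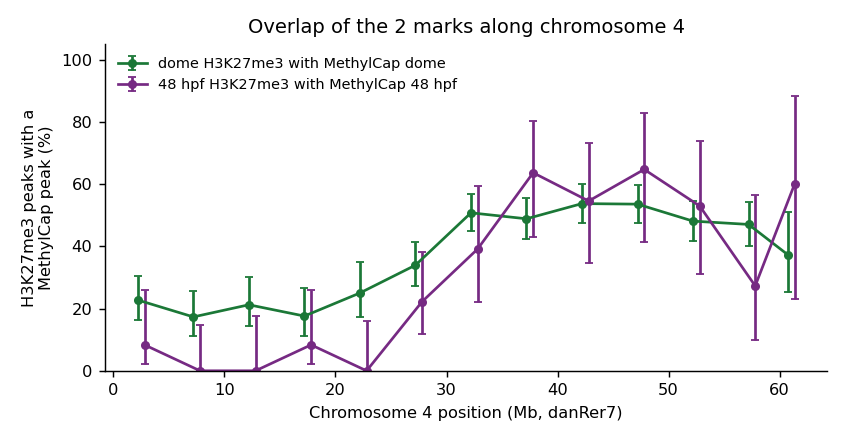
Percentage of H3K27me3 peaks with a MethylCap peak of the same stage (vertical axis) in pieces of 5 Mb along chromosome 4 (horizontal axis, Mb on danRer7; the last piece is shorter), with Wilson 95% intervals. For dome the pieces below 25 Mb lie between 17.3 and 25% and those from 30 to 60 Mb between 47.0 and 53.7%; for 48 hpf each piece holds 5 to 36 peaks, so its intervals are wide.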

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

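The tests with the shortened dome list, with exchanged MethylCap lists, and without chromosome 4 against moves of 10 to 50 kb were chosen only after results were seen. For the last of these, the stratified odds ratio and the upper 1% by fold, the deciding bounds were written before the values were seen, although the patterns were noticed in the same data.

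The overlap of H3K27me3 with MethylCap peaks lay above moved positions at dome (ratio 1.94) and below them at 48 hpf (0.699); the difference between the stages was not tested, because each stage had 1 library per mark. The MethylCap lists alone do not account for it, since dome H3K27me3 peaks had a ratio of 2.19 (SE 0.050) with the MethylCap list of 48 hpf, and 48 hpf H3K27me3 peaks a ratio of 0.670 (SE 0.048) with that of dome. The dome ratio was 1.85 in the higher-scoring 50% of the lists, a setting that also shortened the MethylCap list, so it is not like the values that follow. Against the full MethylCap list it was 1.09 (SE 0.082) in the 6434 most significant H3K27me3 peaks. That value cannot be told apart from 1 with this precision. In the highest decile by −log10 q, also against the full MethylCap list, the dome ratio was 0.833. This fall in the dome list went with a larger share of peaks found at both stages. The 48 hpf ratio also fell with significance, from 1.18 in decile 1 to 0.31 in decile 9, but was 0.889 in decile 10. With equal peak numbers, which also shortened the MethylCap list, the ratio was 1.94 for dome-only and 0.554 for shared peaks. In the full lists these ratios were 2.35 and 0.589, so the dome-only ratio fell as well. Weaker calls may contribute through either change but were not isolated as a cause. The ratio of the 6434 most significant dome peaks exceeded the 48 hpf ratio by 0.387 (SE 0.048, over chromosomes), compared with 1.24 for the full list. This gap passed the bound of 2 SE, set after results were seen, beyond which the longer list would not account for it. With 1 library per stage, however, the spread between libraries is unknown, so weaker calls and a difference between the developmental stages both stay open.

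Dome-only H3K27me3 peaks overlapped MethylCap peaks more often than peaks shared with 48 hpf. Within strata of similar −log10 q and width the odds ratio, shared against dome-only, was 0.271 (SE 0.020), against 0.325 without strata. The difference therefore held among peaks of similar significance and width. The strata cannot exclude false calls, which would be dome-only at any −log10 q. Few peaks of low −log10 q were shared (1.59% in the lowest decile of the dome list), so the weakest strata carried little information. Without chromosome 4 and against moves of 10 to 50 kb, the ratio was 2.22 (SE 0.023) for dome-only and 0.552 (SE 0.037) for shared peaks. These values argue against regions dense in both marks as the full explanation. A partial contribution was not excluded, since the dome-only ratio was 2.35 with all chromosomes and the main moves. Clustering within 10 kb is not covered by these moves. A background common to the ChIP and the capture libraries, such as repeats or fragments that are recovered well in any library, stays open because an input library was not analysed here. So does a hypothesis of methylated sites with transient H3K27me3 in some cells of the blastula, which whole-embryo peak lists do not test.

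At 48 hpf, H3K27me3 peaks in the upper 1% by fold enrichment (65 peaks) coincided with MethylCap peaks more often than the others did. Their ratio to moved positions was 3.21, against 0.679 for the other peaks. At dome the ratios were close, 2.11 and 1.93. Of those in the upper 1% by fold that held a MethylCap peak, 21.2% (14.7 to 29.7%; 24 of 113) at dome met one in the upper 1% of the MethylCap list by fold, and 35.7% (20.7 to 54.2%; 10 of 28) at 48 hpf. Among the remaining H3K27me3 peaks with a MethylCap peak, 3.51% and 6.80% did. Reads piled up at the same sites in every library, for example at repeats collapsed in the assembly, are therefore a candidate explanation for part of the strongest sites, and the very narrow regions of high fold named among the results are best read with that in mind. Sites with both marks would give the same values, so a biological explanation was not excluded.

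Peaks were also called on the mitochondrial genome, which carries no histones and was left out of all comparisons. There were 5 in the H3K27me3 list of dome, with folds of 1.3 to 1.8 against a median of 3.15 on the chromosomes. There were 7 in the MethylCap list of dome (folds 2.53 to 8.58) and 4 in that of 24 hpf (3.27 to 3.82). The H3K27me3 list of 48 hpf held 2, with folds of 2.09 and 2.46, and the MethylCap list of 48 hpf held 0.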

How the results depend on the processing

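The repeats without chromosome 4 and with moves of 10 to 50 kb were tests chosen after the data were examined; the others were set beforehand. The ratios to moved positions kept their side of 1, except that of MethylCap overlap in 48 hpf-only peaks (0.991, range 0.906 to 1.09). With equal peak numbers 2 orders between values turned: dome H3K27me3 peaks were then shared slightly more often than 48 hpf peaks, and dome MethylCap peaks slightly more often with 48 hpf than with 24 hpf. Equal list lengths bring the 2 H3K27me3 shares close together by construction, so their order gives no information on the stages. The difference in MethylCap overlap between 48 hpf-only and shared peaks, 1.2 percentage points with an interval that includes 0, was -0.039 with the stricter overlap and 2.15 (0.311 to 3.99) without chromosome 4. Over the 11 main values, 38 of the 70 recomputed values lay outside the 95% counting interval of the main value, and 32 inside it; these intervals are narrow at these numbers of peaks. Where the alternative's construction (a stricter overlap, or fewer peaks) does not show the cause, the cause was not tested. With an overlap of at least 50% of the shorter peak, sharing of H3K27me3 was 14.5% of dome and 68.4% of 48 hpf peaks, and of MethylCap 79.7% (dome with 24 hpf), 57.4% (dome with 48 hpf) and 46.1% (24 with 48 hpf). The marks then overlapped in 24.7% of dome (ratio 2.30) and 10.1% of 48 hpf peaks (ratio 0.763), and dome-only exceeded shared peaks by 14.6 percentage points. With the higher-scoring 50% of each list, H3K27me3 sharing was 17.7% and 80.7%, MethylCap sharing in the same order 67.0%, 50.8% and 38.2%, the marks overlapped in 18.2% of dome (ratio 1.85) and 7.30% of 48 hpf peaks, and the excess of dome-only peaks was 12.4 points. Equal peak numbers gave H3K27me3 sharing of 52.2% and 49.4%, MethylCap sharing of 62.3%, 63.0% and 57.8%, and 22.1% of dome peaks with both marks (ratio 1.1, an excess over moved positions smaller than 2 times the SE of 0.082 found when the dome H3K27me3 list alone was shortened). Joining peaks within 1 kb gave 15% for dome H3K27me3, 86.0%, 65.1% and 54.8% for MethylCap, and 30.9% with both marks at dome (ratio 1.87). The dome ratio was 2.0 with independent placement and 1.87 with moves of 10 to 50 kb. Without chromosome 4, MethylCap sharing was 82.5% (dome with 24 hpf) and 48.0% (24 with 48 hpf), and the marks overlapped in 28.7% of dome peaks (ratio 1.89). Keeping all sequences added only the mitochondrial genome, since the lists hold no other unnumbered sequence, and moved none of the main values. The alternatives planned for promoters, gene lists and CpG content were not run, because a genome and an annotation of danRer7 were not used here. Depth was unknown, so it could not be matched between libraries, and equal peak numbers are only a stand-in for it.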

Other observations

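The division of chromosome 4 and the repeats of the central MethylCap maximum were tests chosen after the result was seen.

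The distal part of chromosome 4 held a dense set of dome H3K27me3 peaks, most of them without a 48 hpf peak. From 30 Mb to the end there were 45.1 dome H3K27me3 peaks per Mb and 3.65 peaks of 48 hpf per Mb, whereas below 25 Mb there were 20.6 and 4.32, and on the other chromosomes 23.1 and 4.77. Of the distal dome peaks 6.84% had a 48 hpf peak, against 16.7% below 25 Mb and 16.0% on the other chromosomes. Of the distal 48 hpf peaks 82.9% had a dome peak, against 75% below 25 Mb. MethylCap dome peaks were also denser there (215.8 per Mb) than below 25 Mb (124.6 per Mb) and on the other chromosomes (161.9 per Mb).

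Relative to positions 1.5 kb away, a MethylCap maximum at the centre of H3K27me3 peaks was present in the stage-specific peaks of both stages and in the subsets of shared peaks that were tried. In shared dome peaks it was a local rise within a depression, with coverage of 7.21% (SE 0.79) at the centre and 7.13% (SE 0.37) at 8 kb after it. In shared peaks the centre exceeded the positions 1.5 kb away by 3.58 percentage points (SE 0.74) at dome and by 3.45 (SE 0.60) at 48 hpf. In dome-only peaks the excess was 13.4 points (SE 0.45), and in 48 hpf-only peaks 3.11 (SE 0.41), close to that of the shared peaks. Without the highest decile of each list by −log10 q the excess in shared peaks was 3.42 (SE 0.76) and 3.22 (SE 0.67), and without chromosome 4 it was 2.97 (SE 0.43) and 2.94 (SE 0.32).

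MethylCap regions differed in H3K27me3 by the stages at which they were called. Of the regions called at all 3 stages, 6.31% met a dome H3K27me3 peak, 2.19 times the share for moved positions. The ratio was highest for regions called at dome and 48 hpf (2.37), lowest for those called at 24 hpf alone (1.04), and higher for 48 hpf alone (1.82) than for dome alone (1.47), so it did not follow the number of stages. For the 48 hpf H3K27me3 list the lowest ratio was 0.457 (24 hpf alone), and 6 of the 7 patterns of stages lay below moved positions by more than their counting intervals. The exception was regions called at dome and 48 hpf, of which 66 of 10850 (0.608%, 0.478 to 0.773%) met a 48 hpf H3K27me3 peak, against 0.667% for moved positions.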
